A study of Caenorhabditis elegans with 2 samples.

How the data were processed

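Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Caenorhabditis elegans larvae, per the labels. The worms were of strain OP207, which carries a fosmid transgene with the zinc finger gene ztf-1 fused to eGFP and further epitope tags, together with an unc-119 marker. Larvae were at the L2 stage, with an age of 28.5 hours, in cultures synchronised from L1 larvae starved after bleaching. Chromatin was sonicated to 200 to 800 bp and precipitated with an antibody against GFP. There were 2 biological replicates in 1 group, so no comparison between conditions was possible. The matching control experiment named in the labels was not analysed here.

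The analysis started from 8 peak lists that the authors deposited, all on assembly ce11 according to the text notes deposited beside them. Each of 4 comparisons by irreproducible discovery rate (IDR, a rank-based measure of how well peaks recur in paired lists) had a ranked list and a thresholded list. They were a series-level list named conservative, a further series-level list named without that word, and a list for each replicate. The peak caller, the aligner and their settings are not given in the sources used here. Which inputs each IDR comparison paired was read from the values. In the ranked list behind the conservative list, 53.9% of entries had in the first of the paired signals an interval of replicate 1's own ranked list, 44.9% had in the second an interval of replicate 2's, and none had one of the other replicate. The conservative list is therefore called the replicate-compared list below, and the further series-level list the pooled list. Each thresholded list held exactly the entries of its ranked list with an IDR of 0.01 or less.

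The deposited signal value of a peak is the authors' own measure of its strength, with no unit stated, and it was used only to rank and describe peaks within a list. The −log10 q-value of each peak is that of the authors' peak caller, read from its place in the deposited narrowPeak columns, which have no header, and the ranked lists also hold −log10 IDR values. No file used here gives read counts, so the sequencing depth is unknown, and the precision of a single peak's signal cannot be given.

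Overlapping entries of a list were merged (1 bp or more), keeping the summit with the highest signal. The replicate-compared thresholded list served as the main list. The background was every merged peak of the replicate-compared ranked list that overlapped no peak of the 4 thresholded lists. These are regions that were called but did not pass. It is a loose background, since the ranked list covered 36.4% of the genome and its entries had a median q-value of 0.939. Of the background summits, 19.7% lay within 500 bp of a protein-coding start, close to the 18.7% of random positions. Gene models came from Ensembl release 115 for assembly WBcel235, which is the same sequence as ce11, and sequence came from the RefSeq copy of that assembly. All peak ends lay within the reference chromosomes. Coordinates are 1-based. A summit was counted at a gene start if it lay within 500 bp either side of the start of a protein-coding gene. Peaks were assigned to the nearest protein-coding start within 1000 bp for the gene lists, and to noncoding genes whose extent lay within 100 bp of the peak interval. Autosome arms were the first and last of 3 equal parts of each autosome.

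Shares were compared by two-sided Fisher's exact tests, overlaps of lists by one-sided Fisher's exact tests over all ranked regions, and medians and means by two-sided permutation tests with 100000 resamples, whose smallest possible p is 1e-05. Families of tests were adjusted by the Benjamini-Hochberg method at 0.05. Intervals on shares are exact Clopper-Pearson intervals at 95% and cover counting error only. Peaks are not independent replicates, so these p-values describe how the listed peaks differ from other called regions, not how a new experiment would vary. The 20 gene lists were ribosomal proteins, translation factors, proteasome, oxidative phosphorylation, histones, collagens, heat shock, nuclear receptors, homeobox, ztf zinc fingers, bHLH, immune effectors, heterochronic genes, cell cycle, and markers of intestine, body wall muscle, pharynx, neurons, hypodermis with seam, and germline. Their background was all genes assigned to ranked peaks by the same rule. All 2080 distinct words of 6 bases, with reverse complements joined, were counted in 100 bp around summits. They were compared with ranked peaks of the same promoter status and the same 5% bin of GC content, 10 per peak, by one-sided Fisher's exact tests.

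Apart from the tests and alternatives listed last here, the grouping, the tests and the gene lists were fixed before the data were examined. Genes were named by a rule fixed at the same time. It took ztf-1, the nearest protein-coding gene start or the overlapped noncoding gene of the 25 strongest main peaks, up to 4 members of each gene list that passed, and genes at main peaks found in the lists of both replicates. Other genes named below belong to counts of few members or were chosen after their values were seen. Alternatives covered the peak list, the threshold, leaving out each replicate, window sizes, backgrounds, overlap rules and word length. IDR thresholds of 0.05 and 0.001, a q-value of 0.05 or less, starts of all transcripts, the tests of gene features and of chromosomes other than X, and the peak lists tried for arms, GC content, gene features, chromosomes and the ztf-1 locus were chosen after seeing the data. So were the tests on neighbouring peaks, codon use, matched GC content, the stretch around ztf-1, short words and picking by signal in both replicates.

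The word, gene list and permutation tests were tested on simulated data before use. A word planted at 20% of 214 simulated summits passed in 10 of 10 runs, and one planted at 10% passed in 6 of 10 runs. In 10 runs without a planted word, no run had a word past the threshold. Gene lists were planted only from those with 20 or more genes at ranked peaks. Such a list with 4 members among 98 genes passed in 81 of 100 runs, and one with 2 members in 0 of 100. Counts that small were thus not detectable for lists of that size, and smaller lists were not simulated. No list passed in any of 100 runs without planting. For the distance test, 5 of 100 runs without a difference gave p of 0.05 or less. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.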

Results

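Binding of the tagged zinc finger protein ZTF-1 was mapped by anti-GFP ChIP-seq in L2 larvae of a transgenic strain, in 2 biological replicates of whole animals aged 28.5 hours. With 1 group, the questions the design poses are where in the genome the tagged protein was found, and how far the replicates gave the same sites. The main list, from the comparison of the replicates, held 238 entries with a median signal of 96.96, which merged into 214 peaks. Only 26 of the 214 peaks had a deposited q-value of 0.05 or less, and the median q-value of the entries was 0.304. The pooled list held 156 merged peaks, the list of replicate 1 held 18 and that of replicate 2 held 17. Read counts were not used here, so the depth behind each signal is unknown.

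The highest peak in the replicate-compared list lay 287 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit, with its summit at position 3867567 of chromosome III and a signal of 220.7. It was followed by peaks 38 bp upstream of tasp-1 (III, 10759269, signal 217.0), 172 bp upstream of cdc-48.1, which encodes a p97-type AAA ATPase (II, 10563579, 204.2), and 172 bp upstream of F44E5.5, an HSP70 family gene (II, 11759490, 203.0). The fifth-ranked summit lay in an intergenic region 1784 bp upstream of F20B6.9 (X, 4209269, 197.8), and the next beside sls-2.4, a gene for an SL2 spliced leader RNA, 560 bp upstream of egg-5 (I, 4172149, 184.8). Others among the 25 strongest lay upstream of R107.5 (253 bp, signal 173.6), of cox-5A, a cytochrome c oxidase subunit gene (269 bp, 173.1), and of rpl-15, another large-subunit ribosomal protein gene (351 bp, 162.6). All 25 had a q-value of 0.0189 and all 25 overlapped the pooled list. Ranked by the signal of replicate 2 alone, the rpl-15 peak was at place 372, against place 9 in the main list. By that of replicate 1 alone, the 3′ UTR peak of hsp-1 was at place 192, against 23. The places in a single replicate count ranked peaks beyond the main list, so the 2 scales differ.

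Peaks 176 bp from the start of Y55F3AR.2 (signal 158.0), 52 bp from lrpr-1 (155.6), 110 bp from tos-1 (149.3), 213 bp from W04C9.4 (137.0) and 33 bp from K10D2.5 (132.1) were likewise just upstream of genes. The cux-7 summit lay in its 5′ UTR, 8 bp from the start (147.5), and the pcf-11 summit also in a 5′ UTR (148.9), in a peak with the lincRNA gene linc-2 within 100 bp of its interval; pcf-11 encodes an mRNA cleavage factor. Away from starts, summits fell in an intron of mom-1, a porcupine family gene of Wnt secretion (155.6), and in an intron of pqn-41 (136.5). Intergenic summits lay 2770 bp upstream of T04C4.3 (156.5), downstream of W02H3.3 (148.2), at linc-128 upstream of the calmodulin gene cmd-1 (145.9), and 683 bp upstream of the 14-3-3 gene ftt-2 (144.4). The chaperone gene hsp-1, which encodes the constitutive HSC70, had peaks at both ends, with signals of 133.0 at 363 bp upstream and 135.1 in its 3′ UTR. The peak nearest C47E8.4 had its summit in an intron of hsp-90 (136.8).

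**Figure D1:**
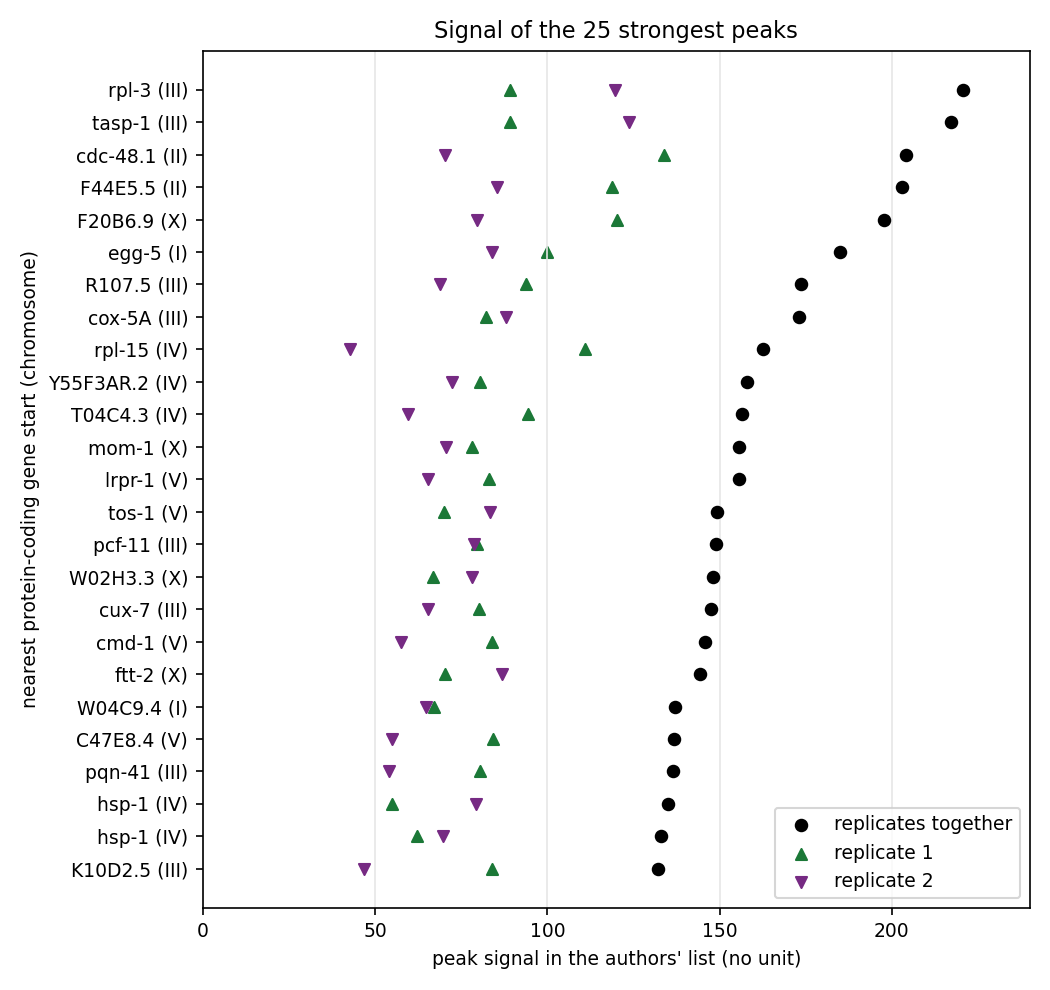
Signal (horizontal axis, no unit) of the 25 strongest peaks of the replicate-compared list, one line per peak, named by the nearest protein-coding gene start. Black circles give the signal with the replicates together, which falls from 220.7 at rpl-3 to 132.1 at K10D2.5, and triangles give the strongest overlapping ranked peak of each replicate alone.

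How far the replicates gave the same sites was compared through their own lists. In both replicates the thresholded lists held the peaks at rpl-3, tasp-1, F44E5.5, F20B6.9, sls-2.4, R107.5, mom-1 and pcf-11. These were 8 of the 18 peaks of replicate 1 (44.4%, 95% interval 21.5 to 69.2%) and 8 of the 17 of replicate 2, where chance would give 0.0108 (one-sided Fisher's exact p = 1.02e-22). Of the 214 main peaks, 27 were in either replicate's list, and 20 of those were among the 25 strongest. The main and pooled lists, which come from largely the same ranked regions, shared 122 of 214 peaks (57.0%, interval 50.1 to 63.7%), an overlap that their common source brings with it. For rpl-3 the signal was 89.2 in replicate 1 and 119.6 in replicate 2, and for rpl-15 it was 110.9 and 42.9.

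Across 211 main peaks with a ranked peak in both replicates, the median signal was 54.1 in replicate 1 and 46.7 in replicate 2. The log2 signals had a Pearson r of 0.20 (permutation p = 0.00313), while Spearman's rho was −0.05 (p = 0.477), so no shared order of peaks was found by rank. These correlations are across peaks of 1 list, and peaks are not independent replicates. Over 10457 ranked regions with a signal in both, rho was 0.256 (p = 1e-05, the smallest possible).

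Gene starts were over-represented among the summits. Of 214 summits, 66 (30.8%, interval 24.7 to 37.5%) lay within 500 bp of a protein-coding start, including those of rpl-3, tasp-1, cdc-48.1 and cox-5A, against 19.7% of 43101 ranked peaks outside the thresholded lists (odds ratio 1.82, two-sided Fisher's exact p = 9.70e-05). Each summit was then counted in 1 of 7 features, with upstream and downstream kept for summits inside no protein-coding gene. Such summits within 500 bp upstream made up 15.9% against 6.44% of the background (adjusted exact p = 1.23e-05 over 7 features). With summits inside other genes counted too, 19.6% lay within 500 bp upstream of a start against 8.37%. Summits in 5′ UTRs made up 4.67% against 1.52% (adjusted exact p = 0.00324). The 500 bp downstream of genes held 8.88% against 3.87% (adjusted exact p = 0.00227), and coding sequence held fewer summits, 23.8% against 34.9% (adjusted p = 0.00188). Shares in introns (26.6% against 29.1%), 3′ UTRs (3.27% against 2.78%) and intergenic sequence (16.8% against 21.3%) did not pass, with adjusted p of 0.526, 0.673 and 0.157. Among the 26 peaks with a q-value of 0.05 or less, 61.5% lay at a gene start (interval 40.6 to 79.8%). The median distance to a start was 1182 bp against 1534 bp (permutation p = 0.0227), but it was 1632 bp in the pooled list (p = 0.569). At IDR 0.05 the coding share turned above its background, 39.4% against 34.8% (adjusted exact p = 0.00849), and the downstream share (4.26% against 3.89%, 0.642) and the 5′ UTR share (2.24% against 1.52%, 0.140) did not pass, while the intergenic share fell below its background (14.1% against 21.4%, 8.32e-08). The downstream and 5′ UTR calls were each lost in 5 of 8 alternatives.

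**Figure D2:**
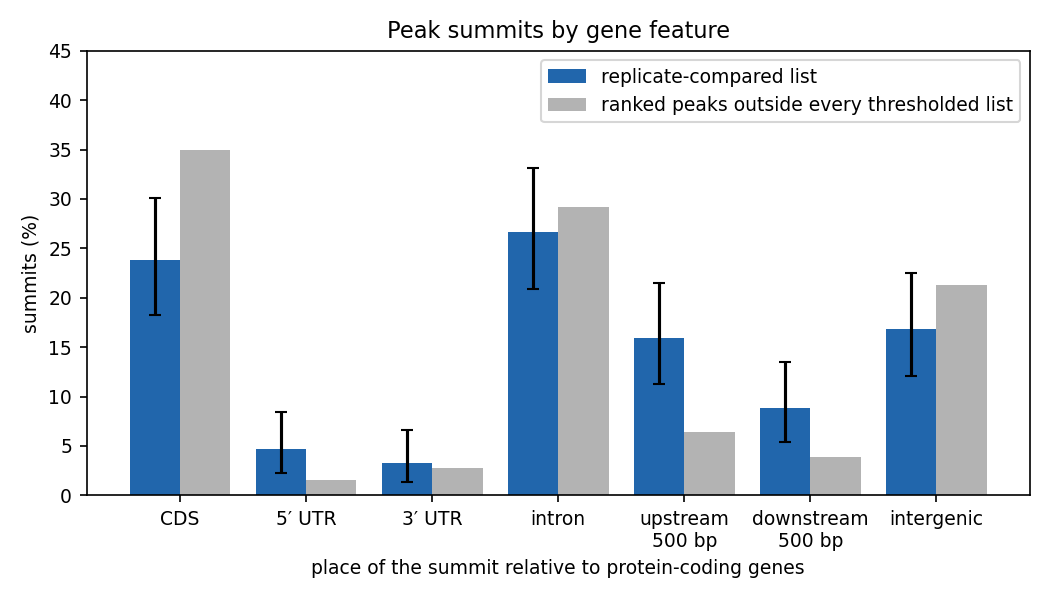
Share of summits (vertical axis, %) by gene feature, for the 214 peaks of the replicate-compared list (blue, with exact 95% intervals) and for ranked peaks outside every thresholded list (grey). Summits within 500 bp upstream of genes, and inside no protein-coding gene, make up 15.9% of the list and 6.44% of the ranked peaks. Those in coding sequence make up 23.8% and 34.9%.

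Among gene lists fixed before the data were examined, ribosomal protein genes stood out. They made up 4 of the 98 genes whose start was the nearest to a summit and within 1000 bp of it. Among the other genes at ranked peaks the share was 0.378% (odds ratio 11.2, adjusted exact p = 0.0132 over 20 lists). The members were rpl-3 (signal 220.7), rpl-15 (162.6), rpl-35 (119.7, summit 475 bp upstream) and rpl-12 (118.1, 11 bp upstream). The list of neuronal genes had egl-3, a neuropeptide-processing protease gene, and unc-25, the gene for GABA synthesis, with an adjusted exact p of 0.121. Collagens had 3 genes (col-171, col-50 and lon-3, adjusted exact p = 0.517). There was 1 gene each for oxidative phosphorylation (cox-5A, 0.519), heat shock (hsp-1, 0.517) and cell cycle (pcn-1, the PCNA gene, 0.517). The heat shock list was made by gene symbol (hsp-), so it did not count F44E5.5, the HSP70 family gene with a strong peak just upstream. With the nearest start within 1000 bp, the other 14 lists had no gene and an adjusted p of 1.00. They were translation factors, proteasome, histones, nuclear receptors, homeobox, ztf zinc fingers, bHLH, immune effectors and heterochronic genes. Also among them were the markers of intestine, body wall muscle, pharynx, hypodermis with seam, and germline. At any distance, eef-2 (translation factors), lin-14 (heterochronic), and ceh-41 and ttx-1 (homeobox) were the nearest starts of peaks, and none of these lists passed. A gene was not counted by either rule where another start lay nearer the summit. With every start within 2 kb, eef-2, rpt-1 (proteasome), his-72 (histones) and clec-196 (immune effectors) were counted, and none of their lists passed. By that rule hsp-60 and hsp-90 joined hsp-1 in the heat shock list. The ribosomal call was lost in the list of replicate 2 alone (adjusted exact p = 0.292), at IDR 0.001 (0.0709) and with the nearest start at any distance (0.0571). With the nearest start at any distance the neuronal list passed instead by the same test (cat-2, egl-3, unc-25 and unc-64, adjusted exact p = 0.00903).

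Small nuclear and nucleolar RNA genes were also found at peaks more often than at ranked peaks. Genes for snoRNAs lay at 8 peaks (3.74%, interval 1.63 to 7.23%) against 0.422% of the background (odds ratio 9.16, adjusted exact p = 3.66e-05 over 7 biotypes), among them F39B2.14, with the summit inside it and in the 5′ UTR of tmem-107 (signal 116.6) and ZK994.7 in an intron of pxn-1 (115.7). Genes for snRNAs lay at 4 peaks (1.87% against 0.146%, adjusted exact p = 0.00122): sls-2.4 (184.8), sls-2.1 (115.1), R07E5.16 (97.8) and T11F9.15 (95.7). Other noncoding RNA genes lay at 29 peaks (13.6% against 6.81%, adjusted exact p = 0.00126), including rpr-1, the RNA subunit gene of RNase P, in an intron of ints-8 (117.7). Genes for miRNAs lay at 3 peaks (cel-mir-51, cel-mir-52 and the cluster with cel-mir-54 to cel-mir-56; 1.40% against 0.248%, adjusted exact p = 0.0305). Shares for lincRNA (2 peaks) and tRNA genes (2 peaks) did not pass, with adjusted exact p of 0.211 and 0.765. For rRNA genes there were 0 main peaks and 0 background peaks, so their share could not be tested. None of these 4 calls held in either single-replicate list: no snoRNA or miRNA gene lay at a peak there, and adjusted exact p was 0.175 and 0.185 for snRNA genes and 0.757 and 0.612 for other noncoding RNA genes. Among peaks with a q-value of 0.05 or less there was again no snoRNA or miRNA gene, adjusted exact p was 0.133 for snRNA and 0.227 for other noncoding RNA genes, and the miRNA call was also lost in the pooled list (2 peaks, 0.104).

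Peaks were spread over all 6 chromosomes. Chromosome III, which carries rpl-3, tasp-1, R107.5 and cox-5A, held 45 of the 214 peaks (21.03%, interval 15.8 to 27.1%) against 14.3% of the background (adjusted exact p = 0.0471), a call that did not pass in 5 of 8 alternatives, all of them smaller lists, where the share was 21.5 to 30.8%. The X chromosome held 31 (14.5% against 17.7%, exact p = 0.243). Autosome arms held 138 of 183 autosomal peaks (75.4%, interval 68.5 to 81.5%) against 66.4% (exact p = 0.00950). In the pooled list the arm share was 73.7% (exact p = 0.0806), and at IDR 0.001 it was 65.6%.

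Summits were rich in G and C. The mean GC content in 100 bp was 46.3% ± 8.58 (SD, n = 214) against 39.3% ± 8.36 in the background (permutation p = 1e-05, the smallest possible), and 39.4% in flanks 300 to 400 bp from the same summits. Around the rpl-3 summit, positions 3867537 to 3867597 of chromosome III, in the 500 bp upstream of the gene, read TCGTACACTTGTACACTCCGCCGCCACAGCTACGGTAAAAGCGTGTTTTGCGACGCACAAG. Around the tasp-1 summit, positions 10759239 to 10759299 of the same chromosome, also upstream of the gene, read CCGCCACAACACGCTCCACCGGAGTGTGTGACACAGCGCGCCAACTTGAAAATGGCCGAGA. No word of 6 bases passed against ranked peaks matched on GC content and promoter status (0 of 2080 by Fisher's exact test with Benjamini-Hochberg adjustment), and 136 had an unadjusted p of 0.05 or less. The top words were AGCGCG and CATATA, each at 7.94% of summits against 2.52% (adjusted exact p = 0.132). Against unmatched ranked peaks 86 words passed. In the 107 peaks with the highest signal 3 passed, CGCGCA, AGCGCG and CCGCGC, with CGCGCA at 14.95% of summits against 2.90% (adjusted exact p = 0.00211).

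No peak of any thresholded list lay within 20 kb of ztf-1 itself, the tagged gene, which spans positions 8787092 to 8792351 on the minus strand of chromosome III. The replicate-compared ranked list had 1 peak in that window, with a signal of 38.8 at position 8810857. Windows of the same size at 10000 random places had a median of 20 ranked peaks, and 99.8% of them had as many or more. Around ztf-1 the ranked list had no peak from position 8766449 to 8810586, a stretch of 44.1 kb with 13 whole protein-coding genes, and this was the seventh longest of 43342 stretches without a peak. Within 50 kb of the gene there were 23 ranked peaks, where random windows had a median of 47. The unc-119 locus, whose gene the transgene also carries, had 17 ranked peaks within 20 kb against a random median of 21, and likewise no peak of a thresholded list.

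**Figure D3:**
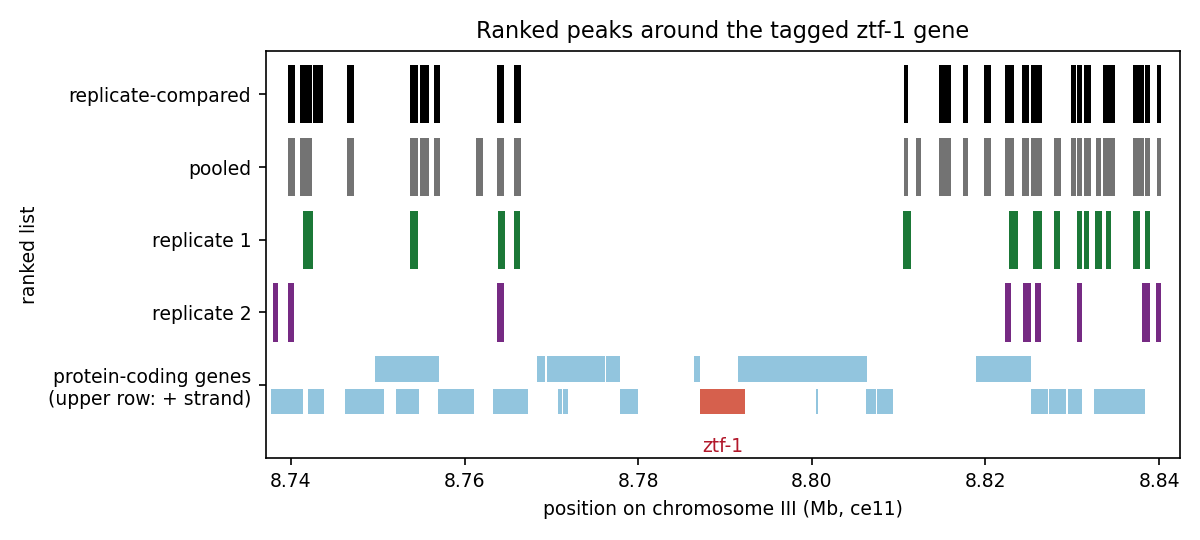
Merged ranked peaks of the 4 lists (upper 4 lanes) and protein-coding genes (lowest lane) along chromosome III, 50 kb either side of ztf-1 (red), in Mb of ce11. No list has a ranked peak across ztf-1, and the stretch without peaks in the replicate-compared list runs from 8766449 to 8810586.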

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

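Tests at IDR 0.05, at IDR 0.001, at a q-value of 0.05 or less, of gene features, of chromosomes other than X, and of the arm share and GC content in other peak lists were chosen after seeing the data, as were starts of all transcripts and other lists at ztf-1. No setting gave a peak of a thresholded list at ztf-1, which with so few peaks says nothing about stability. The gene-start excess kept its direction and passed in 16 of 16 alternatives (15.4 to 61.5% of summits), GC content in 11 of 11, and the overlap of the replicates' lists in 4 of 4. An IDR of 0.01 is the deposited threshold, so using it changed nothing.

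There were 107 peaks in the upper part of the list by signal, 939 at IDR 0.05, 37 at IDR 0.001, 26 at a q-value of 0.05 or less, and 17 to 18 with a replicate left out. The replicate rho turned to 0.256 over all ranked peaks. The median distance to a start was 1632 bp in the pooled list, 1497 bp at IDR 0.05, and 404 to 432.5 bp with a replicate left out (permutation p 0.0512 without replicate 1). The coding share turned to 39.4% at IDR 0.05. The downstream share passed in 3 of 8 alternatives and the 5′ UTR share in 3 of 8; without a replicate their adjusted exact p was 0.195 to 0.267 and 0.267 to 0.337. Gene lists past the threshold, 1 in the main list, numbered 2 at IDR 0.05, 0 at IDR 0.001, 3 with every start within 2 kb, and 0 to 1 with a replicate left out.

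Noncoding biotypes past the threshold, 4 in the main list, numbered 2 at IDR 0.001 (snoRNA and lincRNA), 1 at a q-value of 0.05 or less (lincRNA, not among the 4; adjusted exact p = 0.0223), and 0 with either replicate left out. Peaks at snRNA genes fell to 0 with the summit inside the gene. Peaks at snoRNA genes were 0 with either replicate left out and at a q-value of 0.05 or less. Peaks at miRNA genes were 0 in these settings, at IDR 0.001 and in the 107 peaks with the highest signal. Calls absent from the main list also came up for tRNA genes at IDR 0.05 (14 peaks, adjusted exact p = 0.0109), for heat shock genes at IDR 0.05 (0.0140) and within 2 kb (0.00825), for neuronal genes within 2 kb (0.00291), and for fewer peaks on chromosome V in the pooled list (13.5% against 21.5%, 0.0427). The X share was 12.8% at IDR 0.05, past the threshold (exact p = 3.89e-05). The arm share passed with the first and last of 4 equal parts (62.8% against 48.9%, exact p = 1.93e-04) and at IDR 0.05 (74.2% against 66.2%, 1.09e-06). It was 73.7% in the pooled list, 74.2% in the 107 peaks, 72.7% at a q-value of 0.05 or less, and 73.3 to 76.9% with a replicate left out, none past the threshold, and 65.6% at IDR 0.001, below its background.

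Words past the threshold, 0 in the main list by Fisher's exact test with 136 at an unadjusted p of 0.05 or less, numbered 7 in 200 bp, 4 against flanks, 86 against unmatched ranked peaks, 3 in the 107 peaks, 1 at IDR 0.001, and 0 to 2 with a replicate left out. A single replicate's list has so few peaks that calls can end for that reason alone; for the other changes the cause was not tested. The depth is unknown, so what it limits cannot be stated.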

Other observations

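All tests in this part were chosen after the data were seen. They cover neighbouring peaks, short words, codon use, matched GC content and picking by signal in both replicates. At ztf-1 they cover repeated words, chance placing and extra copies. The reading of the regions with the highest summed signal as undecided also came after the results were seen. Main peaks lay close together more often than ranked peaks. Of the 214 peaks, 31 (14.5%) had another within 10 kb, where 10000 draws of ranked peaks from the same chromosomes gave a median of 8 (95% range 2 to 18; permutation p = 0.0001, the smallest possible). They formed 15 groups, and 1 group had 3 peaks: it lay over the divergent HSP70 genes F44E5.4 and F44E5.5, with signals of 203.0 between the genes, 97.2 downstream of F44E5.5 and 89.8 downstream of F44E5.4. Pairs lay at hsp-1, at cmd-1 (145.9 and 101.0), nearest the start of the tyrosine hydroxylase gene cat-2 (110.4 with the summit inside cat-2 and scc-2, 110.2 with the summit in scc-2), at mxl-3 (102.6 and 89.6), and at pde-6 (108.0 and 97.9).

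Different short words lay at several of the strongest summits. Both were picked on these peaks, so the counts there are no test. ACACGCT was the top of 8192 words of 7 bases, none of which passed in the main list (adjusted one-sided exact p = 0.177). It lay in the 100 bp around the summit at 6 of the 25 strongest peaks (rpl-3, tasp-1, cdc-48.1, cox-5A, rpl-15 and lrpr-1), and at 2.65% of the other 189 main peaks. CGCGCA lay at 7 of the 25 (F20B6.9, R107.5, Y55F3AR.2, tos-1, W02H3.3, pqn-41 and hsp-1), and at 6.35% of the others. If either word marked sites of the tagged protein more widely, it could also be in excess at 698 weaker summits that pass IDR 0.05 but are in no thresholded list. There ACACGCT lay at 0.860% against 0.660% of matched ranked peaks (adjusted one-sided exact p = 0.335), and CGCGCA at 3.30% against 2.56% (adjusted p = 0.298). Neither passed, so whether the words go beyond the peaks they were picked on stays open.

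In the main setting ribosomal protein genes were the only gene list that passed, and rpl-3, hsp-1 and cox-5A were among the genes at the strongest peaks. A candidate explanation is a bias of crosslinking or shearing at highly transcribed genes, with the codon adaptation index of a gene, measured against ribosomal protein genes, as a sequence stand-in for its transcription. Among 94 non-ribosomal genes at main peaks the median index was 0.311 against 0.256 for 12502 others at ranked peaks (permutation p = 1e-05, the smallest possible), the value such a bias needs, but true binding at such genes would give it as well. GC content is argued against for the excess at gene starts, since against ranked peaks matched on GC content its odds ratio was 1.98 (95% interval 1.45 to 2.70). Binding and bias stay open, and no biological explanation was tested.

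Of the 31-base words in the stretch without ranked peaks around ztf-1, 1.57% occur more than once in the genome, where random windows of its size had a median of 5.75%, which argues against unplaceable reads. Only 0.511% of protein-coding gene starts lie in stretches as long or longer. This restates the length rank that was already seen, so it is no separate test. It shows that such a placement by chance would be rare at a gene named before the data were examined. A stretch of 44.1 kb lacked ranked peaks in both replicates and held the tagged gene. A candidate explanation is that extra copies of the region in the transgene raise the control there, if the control came from the same strain, so that less passes as a peak. As the control and the ends of the fosmid were not used here, this cannot be told apart from a removal of the region by the authors' filters, and no biological explanation was tested.

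In the main list the replicates' signals did not rise together by rank (rho −0.05), while over all ranked regions rho was 0.256. A candidate explanation is that picking peaks high in both replicates lowers rho. Among the 211 ranked regions with the highest summed log2 signal rho was −0.13, but 186 of them overlapped main peaks, so this is nearly the pattern itself. A simulation of such picking from regions with 1 common correlation gave a median of −0.73 (95% range −0.80 to −0.63, 1000 draws). The main list lay above that range, but so did the real regions picked by the same rule, and the main list was picked by IDR. The simulation therefore argues only against the 1 common correlation it assumed, and does not decide whether picking lowered rho. Picking from regions whose correlation varies stays open, and no biological explanation was tested.

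The longest stretch without ranked peaks, 222.1 kb on chromosome V from position 2344137, was 97.8% repeated 31-base words, and the next, 85.8 kb on chromosome V from position 8813158, held histone genes and was 99.3% repeated. Among the 10 longest, stretches with few repeated words also lay away from ztf-1. They were 47.1 kb on chromosome II (8.07% repeated, 5 whole genes) and 43.2 kb on chromosome IV (1.75%, 4 whole genes). No peak-free stretch at least 0.5 times as long overlapped the chromosome II one in replicate 2, or the 43.2 kb one in replicate 1. The ztf-1 stretch had such an overlap in each replicate, and so did the others of the 10 longest. Among those were 46.5 kb on chromosome IV (19.8% repeated, 3 whole genes) and 41.3 kb on chromosome I (23.4%, 3 whole genes). Recurrence in both replicates was thus not particular to ztf-1.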
